A study of Mus musculus with 4 samples.

How the data were processed

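Gene expression was measured in the hippocampus of mice heterozygous for a knockout of Rp58 (hetero-KO; current symbol Zbtb18, a zinc finger transcriptional repressor with a BTB domain) and of wild-type (WT) control mice, at 4 and at 18 months of age. Per the labels, 3 independent total RNA samples of each group were mixed and purified, and 200 ng of each mixture was labelled with Cy3 and put on a separate Agilent array, so that each of the 4 groups holds 1 array. The age label of the older groups gives 18 months and their titles 1.5 years, while their descriptions give a range of 12 to 18 months; they are called 18 months here. The labels do not give the sex of the mice.

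The deposited scanner files hold spot intensity on a linear scale, not normalized between arrays. Per the file headers, Agilent Feature Extraction 11.5.1.1 with the protocol GE1_1105_Oct12 removed spatial trends, subtracted the negative controls and replaced dim spots by surrogate values. The headers give mouse genome build mm9 (NCBI37), and all coordinates here are in that build. Each array has 62976 spots, of which 59305 are not controls and hold 56605 probes. The authors' deposited table of all samples holds a linear ratio, with no log and no centring per gene. Its 4-month columns equal the processed signal over the array's 75th percentile that the scanner software gives, within 1%. Its 18-month columns have a 75th percentile near 1 as well, but their values are no constant multiple of any of the 4 scanner files (highest correlation of log2 values 0.982), so which arrays they come from is unknown. The medians of the table's columns were 0.107 for WT and 0.103 for hetero-KO at 4 months, and 0.0998 for WT and 0.0987 for hetero-KO at 18 months. The scanner files were used for all results, and the table only as an alternative.

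From the processed signal, log2 values were formed and each array's 75th percentile over non-control spots without outlier marks was subtracted. Levels are given as the signal divided by that percentile. Spots of a probe were averaged, and a probe counted as measured on an array when at least 50% of its spots were well above background by the scanner software's test. A gene was represented by its probe with the highest mean level. Symbols were updated through RefSeq accessions without version, from a table of assembly GRCm38.p6 used for names alone. Of the probes, 32994 matched and 1535 symbols changed; other probes kept the file's name. Of 37047 genes, 27169 were measured on all 4 arrays, 16739 of these with an official symbol.

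With 1 array per group, a comparison of a pair of arrays has no replicate check and no test: genes measured on both arrays with a fold of 2 or more were counted. Where a gene was well above background on only 1 of the arrays, its fold is a bound, the bright level over the higher of the dim probe's own level and the lowest level among probes well above background on the dim array, given as "at least". The genotype difference over both ages and the age difference over both genotypes were tested with an additive model of genotype and age in limma 3.58.1 (R 4.3.3), with eBayes, a variance trend and Benjamini-Hochberg adjustment at 0.05. This fit has 1 residual degree of freedom. It takes any genotype difference that changes with age as error, and its p-values describe the spread among 4 pooled arrays, not among mice. The 28860 genes measured on at least 2 of the 4 arrays were tested; this filter was not fixed in advance, while no filter and a filter on all 4 arrays were alternatives fixed in advance. With simulated data on the same 28860 genes, the genotype test recovered 74.5%, 89.5% and 98.5% of 200 genes changed by 1.5-fold, 2-fold and 4-fold, with 10, 17 and 12 false calls. The simulated noise was normal, with the same SD for all genes of similar level, so that no gene had a spread of its own. These shares may therefore overstate what the test recovers in the real arrays. The genotype by age difference has no residual degree of freedom and is a value alone.

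Fixed lists of genes were described by the median log2 difference of their members measured on all 4 arrays, with its percentile among 10000 random lists of the same size matched on mean level. In every comparison, 27 to 35 of the 54 lists with enough members fell outside the central 95% of random lists, where 2.7 would by chance, so that a percentile by itself separates little. Members that passed the test were counted over all genes tested and adjusted over the list alone. Both counts are against no change, not against random lists, so a shift shared by genes of similar level adds to them. Several lists share members.

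Apart from that filter, the grouping, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took Zbtb18 and, in each comparison, the 10 genes with the largest differences in each direction among genes with an official symbol, measured on all arrays compared, at or above the 25th percentile of levels, and with no other measured probe going the other way. For the differences over both pairs, genes had to go the same way in both and were ranked by the smaller difference. The rule added 3 genes per direction with a bound, 5 per direction for the genotype by age difference and up to 4 members per direction of a list. The results of a few genes that it took, and list results that rest on them, are left out here. The alternatives were quantile and median scaling, normexp on the mean and local background signals with an offset of 50, spots with outlier marks kept, the mean of a gene's probes, no filter or a filter on all 4 arrays, no variance trend, a fit without the other term, the mean in place of a list's median, each array left out, and the authors' table; each kept the main setting's probe of a gene, save the mean of a gene's probes. Counts without X- and Y-linked genes and without the lists of neighbouring regions, choroid plexus and meninges were added after seeing the data. Figures and lists were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The number of arrays limits the precision; the median SD of log2 signal among replicate spots of a probe within an array was 0.0315 to 0.0342.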

Results

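Hippocampal expression was profiled on 4 one-colour arrays, 1 for each combination of genotype (WT or hetero-KO for Rp58, that is Zbtb18) and age (4 or 18 months), each holding RNA pooled from 3 samples. The 75th percentile of the signal was 1975 for WT and 2111 for hetero-KO at 4 months, and 1734 and 1714 at 18 months. The share of spots well above background was 81.9%, 79.5%, 79.0% and 77.9% in the same order. No group had a replicate array, and the number of arrays limits the precision.

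The targeted gene, Zbtb18, was measured by a probe on chromosome 1 at 179380753 to 179380812. Its level was 17.5 in WT and 15.2 in hetero-KO at 4 months, and 18.9 and 21.4 at 18 months. The log2 difference of hetero-KO from WT was −0.20 at 4 months and 0.18 at 18 months, each smaller than the spot error of 0.20 that the scanner software gives. The part of the gene that was removed is not given in the sources used here, and a probe outside that part checks nothing about the genotype labels. The difference between 18 and 4 months was 0.11 in WT and 0.49 in hetero-KO.

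Several genes of the Y chromosome and Xist, the RNA that silences an X chromosome in females, differed between the pools. Eif2s3y, Uty and Ddx3y were not well above background in hetero-KO at 4 months, where they were at least 100-fold, 19.8-fold and 15.8-fold lower than in WT of that age. Xist had levels of 0.164 in WT and 0.231 in hetero-KO at 4 months and was not well above background on either array of 18 months. Kdm5d, also Y-linked, was well above background on all 4 arrays, with levels of 0.0880 and 0.0845 at 4 months and 0.117 and 0.120 at 18 months, and did not follow the other Y-linked genes. In WT at 4 months, Eif2s3y, Uty and Ddx3y stood at 0.51, 0.34 and 0.45 times the geometric mean of the 18-month pools. By these genes and Xist, Kdm5d aside, the hetero-KO pool of 4 months looks female and both 18-month pools male. The WT pool of 4 months looks mixed. The 4-month comparison and all age comparisons thus set pools of different sex makeup against each other. Age and sex makeup cannot be told apart in the age comparisons. The pools of 18 months were close in the Y-linked genes. Without X- and Y-linked genes, a count added after seeing the data, 187 genes were at least 2-fold higher and 172 lower in hetero-KO at 4 months. Only 15 of the 374 genes at least 2-fold apart were X- or Y-linked, so this count had little room to move and does not test sex makeup.

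At 4 months, markers of the striatum were higher in the hetero-KO pool and markers of choroid plexus, meninges and thalamus were lower. All 19 striatum markers were higher, with a median of 0.69; the adenosine receptor Adora2a was higher by 2.27 and Rgs9 by 1.70 on the log2 scale. All 24 choroid plexus genes were lower (median −0.46), as were 16 of 18 meningeal fibroblast markers (−0.27), 17 of 18 thalamus and habenula markers (−0.30) and 18 of 20 endothelial markers (−0.24). Immediate early genes, which neurons switch on within minutes of activity, were higher for 28 of 32 members (median 0.23; Egr2 by 0.88 and Ier5 by 0.56), and dentate granule cell markers were lower for 18 of 22 (median −0.19; Dsp −0.84).

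Among 28187 genes measured on both 4-month arrays, 195 were at least 2-fold higher and 179 at least 2-fold lower in hetero-KO. Single genes that were higher included Prl, the hormone prolactin, 19.9-fold, D7Ertd183e 7.61-fold, Ido1, an enzyme of tryptophan breakdown, 3.85-fold, Sh3rf2 3.82-fold, Igf2os, an antisense transcript of the Igf2 locus, 3.60-fold, Serpina9 3.57-fold and the peptide gene Grp 3.54-fold. Lower in hetero-KO were Cela3b 4.42-fold, Ceacam16 3.63-fold, S100a9, a calcium-binding protein of neutrophils, 3.33-fold, Prr15 2.68-fold, Tmem253 2.66-fold, Gng8 2.61-fold, Abhd12b 2.46-fold, Tac2 2.45-fold, the chloride channel Cftr 2.45-fold and the BMP antagonist Grem1 2.32-fold. Olfr120, Olfr645 and Myzap were well above background in hetero-KO alone and at least 32.8-fold, 27.4-fold and 27.2-fold higher there. These are differences between a pair of pools with no test, and with normexp background the counts were 69 higher and 27 lower.

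At 18 months, reactive astrocyte, border macrophage, complement and microglial lists were higher in hetero-KO, and choroid plexus genes were again lower. All 31 measured genes of reactive astrocytes were higher (median 0.36), as were all 10 markers of border macrophages (0.77), 21 of 22 homeostatic microglia markers (0.22), 14 of 16 complement genes (0.33) and 7 of 8 neutrophil and monocyte genes (0.54). Lcn2, a secreted iron-carrier binding protein of inflammation, was 4.86-fold higher, and Lrg1, the chemokine Ccl8, S100a9 and the inflammasome component Nlrp3 were 2.89-fold, 2.95-fold, 2.73-fold and 2.45-fold higher. All 24 choroid plexus genes were lower (median −0.79), while meningeal fibroblast markers were higher for 13 of 18 members (median 0.40) and red blood cell genes for all 7 (0.27). Different shares of neighbouring tissue in this single pair of pools could contribute to the 18-month differences, which was not tested. The same lists of reactive astrocyte and border macrophage genes had medians of −0.10 and −0.26 at 4 months. Neutrophil and monocyte genes were lower at 4 months for all 8 members (−0.21), complement genes for 10 of 16 (−0.11), disease-associated and aged microglia genes for 19 of 27 (−0.09, against 0.15 at 18 months) and red blood cell genes for 6 of 7 (−0.22). MHC class II genes stood at −0.37 at 4 months and 0.24 at 18 months. These differences between the ages were not tested. Homeostatic microglia markers were higher at 4 months too, for 15 of 22 members (0.06), and interferon response genes were higher at both ages, for 25 of 33 members at 4 months (median 0.11) and 26 at 18 months (0.08). Lymphocyte genes were lower for 9 of 14 members at 4 months (−0.11) and 8 at 18 months (−0.08).

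Of 27412 genes measured on both 18-month arrays, 145 were at least 2-fold higher and 169 at least 2-fold lower in hetero-KO. Igf2os was 4.17-fold, Spaca4 3.26-fold, the matrix protein Fbln2 2.53-fold and the receptor kinase Mst1r 2.49-fold higher, and the glypican Gpc3 was higher by 1.32 on the log2 scale. Genes at lower level in hetero-KO were Lbhd2 by 17.2-fold, Ctxn3 by 10.9-fold, the calcium pump regulator Sln by 7.94-fold, Igfbpl1 by 6.64-fold, the transcription factor Ebf3 by 6.53-fold, Ano2 by 5.18-fold, Calb2, the calcium-binding protein calretinin, by 5.16-fold and Magel2 by 3.77-fold. Eomes, a transcription factor of intermediate neuronal progenitors, was at least 17.3-fold lower in hetero-KO, Ebf2 at least 10.7-fold and Zar1 at least 8.90-fold, while Hoxa2, Olfr384 and Tnmd were at least 15.3-fold, 10.1-fold and 9.36-fold higher. For Lbhd2 the 4-month levels were 0.317 in WT and 0.189 in hetero-KO, and the 18-month levels 2.85 and 0.166. For Sln they were 0.210 and 0.266, and 1.64 and 0.206. For both, hetero-KO at 18 months was near the 4-month arrays, and the WT array of 18 months stood apart. Eomes, Ebf2 and Ebf3 were also highest on that array. For Igfbpl1, Calb2 and Magel2 it was more the hetero-KO array of 18 months that stood apart, at the lowest level. With normexp background 25 genes were higher and 41 lower.

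Over both ages, 3 genes rose in hetero-KO by limma with Benjamini-Hochberg adjustment and 0 fell, among 28860 tested; 1492 were higher and 1817 lower at an unadjusted p under 0.05. Hrh3, the histamine H3 receptor, rose 2.04-fold (log2 1.03 ± 0.04 SE, limma adjusted p = 0.0439), by 1.03 at 4 months and 1.04 at 18 months. The other 2 are transcripts without an assigned function on chromosome 1 and were chosen after their values were seen. Gm29856, with a probe at 179391247 to 179391306, rose 23.8-fold (log2 4.57 ± 0.10 SE, limma adjusted p = 0.0066), and AK156859, at 179406323 to 179406382, rose 16.2-fold (log2 4.02 ± 0.13 SE, adjusted p = 0.0213). Their probes lay 10.5 kb and 25.6 kb from the Zbtb18 probe. No gene passed without the filter on dim probes or without the variance trend, and 9 rose and 5 fell with normexp background. Of these 3 genes, 2 passed with the mean of a gene's probes and 1 without the age term.

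**Figure D1:**
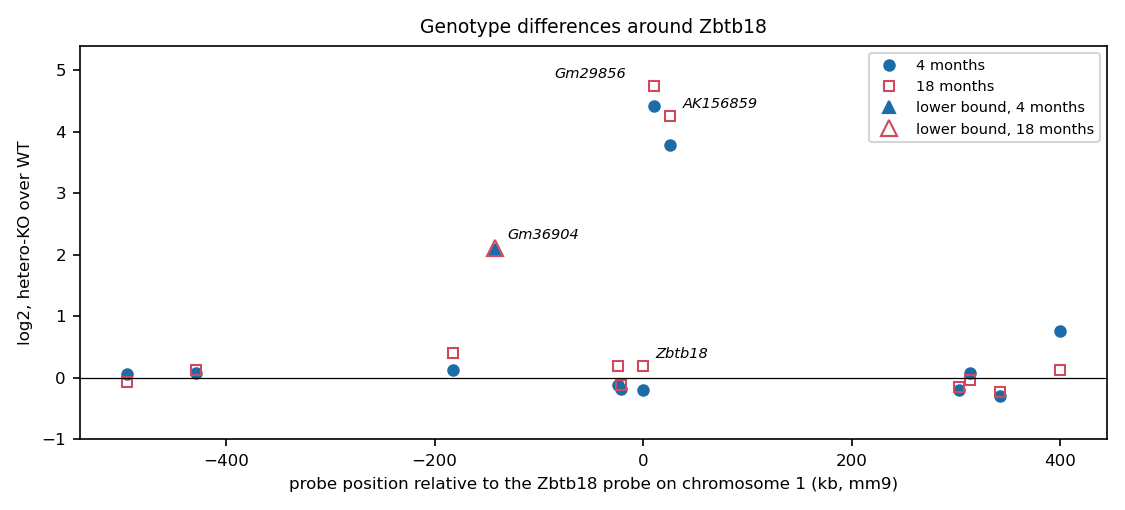
Log2 difference of hetero-KO from WT (vertical axis) against the position of each gene's probe relative to the Zbtb18 probe on chromosome 1, in kb (mm9), at 4 months (filled) and 18 months (open), for genes measured on all 4 arrays; triangles are lower bounds for Gm36904, which was well above background in hetero-KO alone. Gm29856 and AK156859 stand between 3.78 and 4.73 at both ages, and Zbtb18 at −0.20 and 0.18.

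Further genes that were higher in hetero-KO at both ages did not pass: Igf2os by 1.85 and 2.06, Fbln2 by 1.56 and 1.34 and Gpc3 by 1.44 and 1.32 at 4 and 18 months (limma adjusted p = 0.0621 for each). The proneural factor Neurog2 was higher by 1.55 and 1.22, the actin-severing protein Scin by 1.27 and 1.11, the collagen Col12a1 by 0.99 and 1.14, the Notch effector Hes1 by 0.98 and 1.07, and Mst1r by 0.90 and 1.31. Lower at both ages were the transcription factor Zic4 (−1.06 and −1.15), the chemokine Cxcl5 (−1.04 and −1.25), Tmem114 (−0.94 and −1.34), Grem1 (−1.21 and −0.94), Tmprss11a (−0.97 and −0.92), Sult1c2 (−1.20 and −0.91), the chloride channel Ano1 (−0.88 and −0.84), Fam160a1 (−0.80 and −0.93), Acox2 (−0.80 and −0.91) and Cfap73 (−0.78 and −1.05).

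No gene list had a member past the threshold over all genes for genotype. Adjusted over the list alone, 23 of 24 choroid plexus genes fell (median −0.61; Sostdc1 −0.81, F5 −0.79 and Ttr, the thyroid hormone carrier transthyretin, −0.22), 8 of 22 dentate granule cell markers fell (median −0.14; Dsp −0.77 and Npnt −0.77), 11 of 32 immediate early genes rose (0.15; Egr2 0.61 and Ptgs2 0.50) and 10 of 20 glucocorticoid responsive genes rose (0.21; Sgk1 0.48 and Tsc22d3 0.42). Members of a list can shift together on an array, so such counts are not independent results. A different share of choroid plexus tissue in the pools could account for the fall of its genes and was not tested over both ages. By the same adjustment over the list alone, 5 mossy cell markers rose and 1 fell (median 0.11), 4 CA3 pyramidal markers rose (0.16), 4 p53 target genes rose and 1 fell (0.08), 4 potassium channel genes rose and 1 fell (0.03), 3 interneuron markers rose (0.08), and 3 of 19 striatum markers rose (0.30). Of thalamus and habenula markers 1 rose and 4 fell (−0.16; Zic1 −0.87), of CA1 pyramidal markers 1 rose and 2 fell (0.05; Wfs1 −0.73), of CA2 pyramidal markers 1 fell (−0.13), of meningeal fibroblast markers 2 fell (0.11), of reactive astrocyte genes 2 rose (0.16; Cxcl10 1.06), and of synaptic vesicle genes 1 rose and 2 fell (0.08). Klk6 among myelin genes and Tubb3 among progenitor and immature neuron markers rose in this way, and Marcksl1 in the last of these lists fell. The 11 Id and proneural genes named as targets of this repressor in cortex development had a median of −0.03, and 1 of them, Neurog2, rose when adjusted over the list alone. DNA repair (−0.00; 0.01 under quantile normalization), nuclear oxidative phosphorylation (0.03), autophagy (0.02), proteasome (0.03) and heat shock genes (0.09) had 0 members past the threshold either way by limma. Several of these medians average opposite values at 4 and 18 months: 0.15 and −0.10 for CA1 pyramidal, −0.15 and 0.05 for CA2 pyramidal, 0.18 and −0.04 for interneuron, −0.30 and 0.03 for thalamus and habenula, 0.05 and −0.10 for progenitor and immature neuron, and −0.27 and 0.40 for meningeal fibroblast markers.

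**Figure D2:**
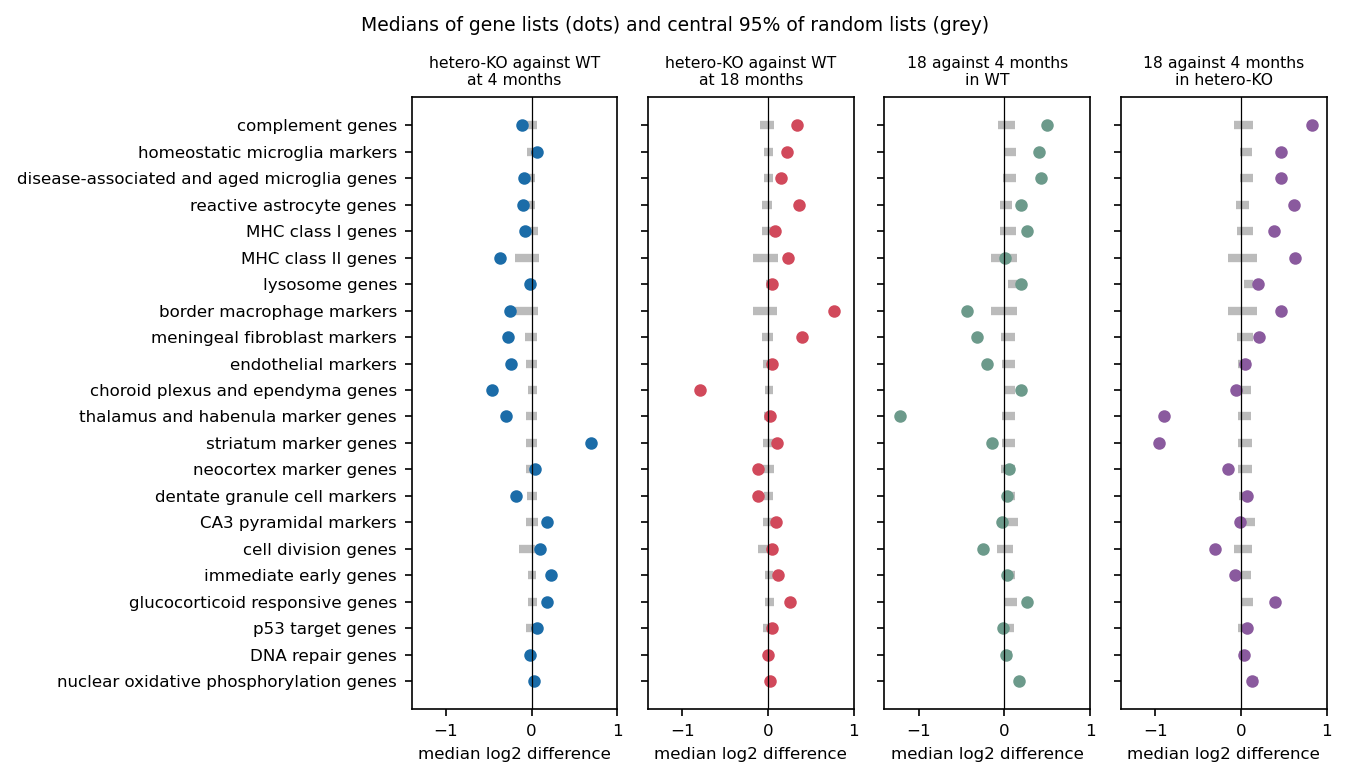
Median log2 difference (horizontal axis) of 22 gene lists in the 4 comparisons of a pair of arrays (dots), with the central 95% of 10000 random lists of the same size and level (grey bars). The striatum dot stands at 0.69 at 4 months, the choroid plexus dots at −0.46 and −0.79, and the thalamus and habenula dots at −1.22 and −0.90 in the age comparisons.

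Between 4 and 18 months, several genes of complement and microglia rose over both genotypes. C4b, a complement component, rose 4.85-fold (log2 2.28 ± 0.09 SE, limma adjusted p = 0.0097), from 4.99 to 21.3 in WT and from 5.04 to 27.7 in hetero-KO. C4a rose 5.13-fold and C3 4.73-fold. Clec7a, a receptor of activated microglia, rose by 2.58 on the log2 scale, the integrin Itgax 5.14-fold and the protease inhibitor Cst7 4.90-fold. Dlk1 rose by 1.58 on the log2 scale and Avp, the peptide vasopressin, 3.50-fold. Syt10, a synaptotagmin, was higher by 2.08 in WT and 3.93 in hetero-KO (limma adjusted p = 0.0513) and Ceacam16 by 1.60 and 4.00 (0.0766), and neither passed.

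The genes that fell most with age over both genotypes included markers of thalamus and habenula. Shox2, a transcription factor, fell by 4.54 on the log2 scale (± 0.35 SE, limma adjusted p = 0.0307). The receptor Vipr2 (−3.15), Opn3 (−3.11), the troponin Tnnt1 (−2.81), Nexn (−2.63), the transcription factor Gata3 (−2.55), the vesicular glutamate transporter Slc17a6 (−2.40), the transcription factor Tcf7l2 (−2.12), the glycine receptor Glra1 (−1.91) and the synaptic vesicle priming factor Unc13c (−1.89) fell as well. Of 18 thalamus and habenula markers, 13 fell over all genes and 14 adjusted over the list alone (median −1.01; Synpo2 −3.01). Striatum markers were lower for 18 of 19 members (median −0.53, from −0.15 in WT and −0.95 in hetero-KO, whose 4-month array was high in them), with 0 past the threshold over all genes by limma and 2 adjusted over the list alone.

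In all, 455 genes rose and 192 fell with age among the 28860 tested by limma with Benjamini-Hochberg adjustment, so that 70.3% of calls were higher; 4861 were higher and 1986 lower at an unadjusted p under 0.05. With quantile normalization 54 rose and 118 fell, and 31.4% of calls were higher. No gene passed without the filter on dim probes or without the variance trend. Values in the authors' table gave the opposite sign for C4a, C4b, C3, Clec7a, Itgax, Dlk1, Avp, Opn3 and Unc13c; its 18-month columns match none of the scanner files.

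**Figure D3:**
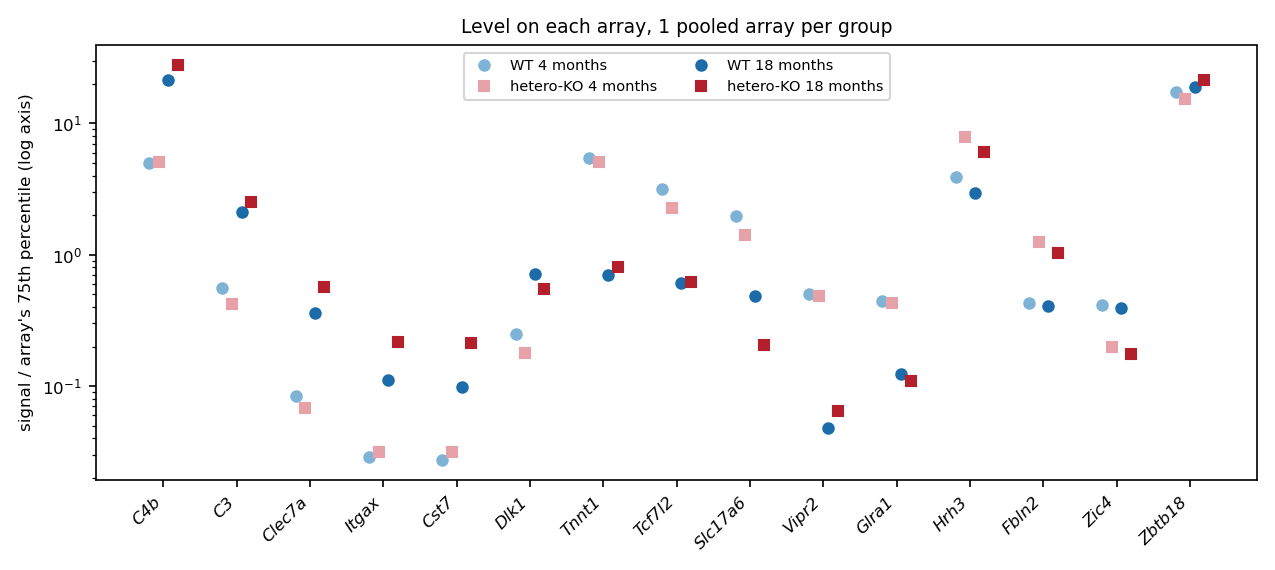
Level of 15 genes on each of the 4 arrays, as the signal divided by the array's 75th percentile (log axis), with 1 point per pooled array. C4b stands at 4.99 and 5.04 at 4 months and at 21.3 and 27.7 at 18 months; Zbtb18 stands between 15.2 and 21.4.

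Of the immune and glial lists, 12 of 22 homeostatic microglia markers rose with age over all genes and 16 adjusted over the list alone (median 0.47; Trem2 0.84 and Tyrobp 0.76). Among disease-associated and aged microglia genes 12 of 27 rose, and 23 adjusted over the list alone (0.38; the chemokine Ccl3 2.22). Of 16 complement genes 6 rose, and 9 adjusted over the list alone (0.63). MHC class I genes rose for 3 of 14 members, 9 adjusted over the list alone (0.33; H2-L 0.47), MHC class II genes for 1 of 8, 2 adjusted over the list alone (0.32, from 0.01 in WT and 0.64 in hetero-KO; H2-DMb1 0.65), and lymphocyte genes for 1 of 14, the immunoglobulin joining chain Jchain, and 3 adjusted over the list alone (median 0.30). Reactive astrocyte genes rose for 5 of 31 members and 14 adjusted over the list alone (0.43; Serpina3n was higher by 1.15 but did not pass over all genes, limma adjusted p = 0.0595). Interferon response genes had 0 members past the threshold over all genes by limma and 4 adjusted over the list alone (median 0.15). Border macrophage markers and neutrophil and monocyte genes had 0 either way by limma (medians 0.08 and 0.21). These medians average opposite differences: border macrophage markers stood at −0.44 in WT and 0.47 in hetero-KO, and neutrophil and monocyte genes at −0.07 and 0.53.

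Lysosome genes rose for 7 of 32 members and 19 adjusted over the list alone (median 0.19; Grn, the progranulin gene, 1.63, and the protease Ctss 0.69). Cytosolic ribosomal protein genes rose for 16 of 50 members and 46 adjusted over the list alone (0.22; Rplp2 0.36). Nuclear oxidative phosphorylation genes rose for 4 of 58 members and 36 adjusted over the list alone, with a median of 0.15 at percentile 10.8 of random lists and of −0.02 under quantile normalization. Glycolysis genes rose for 4 of 20 members, while adjusted over the list alone 16 rose and 1 fell (0.17; −0.03 under quantile normalization; Aldoa 0.40). Glucocorticoid responsive genes rose for 8 of 20, while adjusted over the list alone 11 rose and 2 fell (0.27; Plin4 1.69 and Hif3a 1.11). Oligodendrocyte and myelin genes rose for 4 of 27 and 10 adjusted over the list alone (0.10; −0.00 under quantile normalization; the protease Klk6 1.32).

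Cell division genes had a median of −0.27, with 2 of 26 members lower over all genes and 8 adjusted over the list alone (Top2a −1.52). Oligodendrocyte precursor markers fell for 3 of 14 members, while adjusted over the list alone 5 fell and 2 rose (median −0.12, from 0.05 in WT and −0.19 in hetero-KO; Tmem163 −1.28 and Gpr17 −0.73). Neural stem cell, progenitor and immature neuron markers fell for 0 of 18 over all genes by limma and 4 adjusted over the list alone (−0.20); Dcx, a protein of migrating young neurons, had a difference of −0.66 and did not pass over all genes.

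Of 32 immediate early genes 1 rose and 3 fell, while adjusted over the list alone 7 rose and 9 fell (median −0.03, from 0.03 in WT and −0.07 in hetero-KO; Fos −0.62). Synaptic vesicle and active zone genes rose for 1 of 31 members and fell for 4, while adjusted over the list alone 10 rose and 5 fell (0.10; −0.03 under quantile normalization; Slc17a8 −1.31). Glutamate receptor genes fell for 1 of 22, while adjusted over the list alone 4 rose and 3 fell (0.05; −0.02 under quantile normalization; Gria4 −0.42). GABA receptor genes passed for 0 of 14 over all genes by limma, while adjusted over the list alone 2 rose and 4 fell (−0.07). Postsynaptic scaffold and plasticity genes rose for 2 of 24 and 5 adjusted over the list alone (0.10; Camk2a 0.44).

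Among markers of hippocampal cells, CA3 pyramidal markers fell for 2 of 15 over all genes, and 2 rose and 3 fell adjusted over the list alone (median −0.01; Coch −1.08). CA1 pyramidal markers rose for 1 of 17, and 5 rose and 1 fell adjusted over the list alone (0.04, from 0.23 in WT and −0.04 in hetero-KO; −0.04 under quantile normalization). CA2 pyramidal markers fell for 1 of 12, Pcp4 (−0.68), and 1 rose and 1 fell adjusted over the list alone (median 0.22). Mossy cell markers fell for 1 of 13, and 6 rose and 2 fell adjusted over the list alone (0.13). Interneuron markers fell for 1 of 29, the calcium-binding protein Pvalb (−0.47), and 2 rose and 2 fell adjusted over the list alone (median −0.05, from 0.11 in WT and −0.15 in hetero-KO). Dentate granule cell markers rose for 1 and fell for 1 of 22, and 3 rose and 2 fell adjusted over the list alone (0.06).

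In the remaining lists, members past the threshold by limma over all genes were few. Ttr in the choroid plexus and ependyma list (median 0.09), Ddb1 among DNA repair genes (0.05), Aldoc among astrocyte markers (0.09), Gabarapl1 among autophagy genes (0.06), Bag3 among heat shock and chaperone genes (−0.04) and Psmc3 among proteasome genes (0.10; −0.01 under quantile normalization) rose. Adjusted over the list alone the numbers that rose in these lists were 2, 1, 4, 1, 3 and 8 in the same order, and 1 heat shock gene fell. Btg2 among p53 target genes (0.04; −0.01 under quantile normalization), Col3a1 among collagen and matrix genes (−0.03) and meningeal fibroblast markers (−0.05), and Cux2 among neocortex markers (−0.08) fell. Adjusted over the list alone 1, 3, 2 and 6 members fell in these lists in the same order, and 1 meningeal and 3 neocortex markers rose. Of these medians, several average opposite values in WT and hetero-KO: 0.19 and −0.06 for the choroid plexus, 0.02 and −0.10 for the heat shock, −0.17 and 0.03 for the collagen, −0.32 and 0.21 for the meningeal and 0.05 and −0.15 for the neocortex list.

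Potassium channel genes (0.04; −0.03 under quantile normalization) and circadian clock genes (0.04) each had 1 member that rose and 2 that fell, and adjusted over the list alone 3 rose and 2 fell, and 4 rose and 3 fell. No member passed over all genes by limma among mitochondrially encoded genes (0.13; −0.07 under quantile normalization), genes of mitochondrial biogenesis, dynamics and quality control (0.03; −0.02 under quantile normalization), antioxidant genes (0.09), cholesterol synthesis genes (0.10) and red blood cell genes (0.31). Adjusted over the list alone 3, 1, 10, 5 and 1 of them rose, and 1 antioxidant gene fell. The Id and proneural genes (−0.01), unfolded protein response genes (−0.03, from 0.07 in WT and −0.10 in hetero-KO), endothelial markers (−0.09, from −0.20 and 0.05) and pericyte and smooth muscle markers (−0.17) had 0 members past the threshold by limma either way.

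Within WT, 217 genes were at least 2-fold higher and 231 lower at 18 than at 4 months among 28050 measured on both arrays; within hetero-KO the counts were 303 and 300 among 27399. In WT, Prl was 11.3-fold, Lbhd2 8.98-fold, Sln 7.81-fold and Avp 4.60-fold higher, and Shox2 38.8-fold and Vipr2 10.6-fold lower. In hetero-KO, Ceacam16 was 16.0-fold, Syt10 15.3-fold, S100a8 11.2-fold, S100a9 10.4-fold and Lcn2 8.51-fold higher, and Shox2 14.0-fold, the peptide gene Trh 9.82-fold and Ido1 7.80-fold lower. Across 27169 genes, which are not independent replicates, the age differences in WT and hetero-KO correlated with Pearson's r 0.439 and Spearman's rho 0.447, and the genotype differences at 4 and 18 months with r 0.195 and rho 0.283. The genotype difference at 4 months and the age difference in WT share an array and had r 0.269, where simulated unchanged groups gave 0.499. Their covariance was 0.0224 against 0.0306 simulated. The simulated noise was equal on all 4 arrays and took its SD from the genotype by age differences of genes of similar level. That SD holds any real such difference, so values under the simulated ones do not show a lack of resemblance.

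For the genotype by age difference, the change in genotype difference between the ages was divided by 2, as in the mean contrasts. On this scale 439 genes reached 1.5-fold or more, against 647 for genotype and 1079 for age over the same 27169 genes. The 439 hold array noise together with any genotype by age difference. Single genes are given with the full, undivided change. The genotype difference was greater at 18 than at 4 months for S100a9 by 3.19 on the log2 scale, S100a8 by 3.12, Lcn2 by 2.62, Ceacam16 by 2.40 and Tac2 by 1.93. It was lower at 18 months for Prl (−5.99), Lbhd2 (−3.36), Sln (−3.33) and Ctxn3 (−3.15). No residual degree of freedom remained to test these values. The mean genotype and mean age differences had r 0.0105 across genes.

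**Figure D4:**
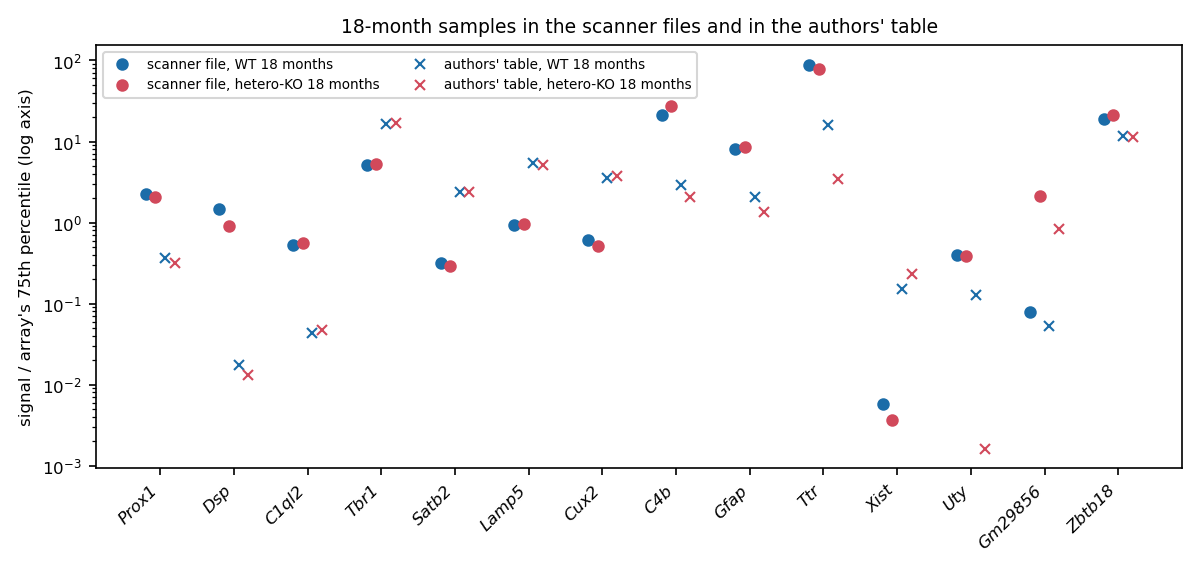
Level of 14 genes at 18 months, as the signal divided by the array's 75th percentile (log axis), in the scanner files (circles) and in the authors' deposited table (crosses). Tbr1 stands at 5.16 and 5.28 in the scanner files and at 16.4 and 16.9 in the table, and Prox1 at 2.27 and 2.04 against 0.364 and 0.314.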

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

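In the following, the tests of exchanged columns, of the sex makeup in the table's columns, of regional shares and of between-array scaling were chosen after the result was seen. The Wilson intervals of all ratios of shares were also added after the ratios had been seen.

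The genotype difference had opposite signs at the 2 ages for 4 of the genes given for their genotype by age difference, by at least 1.5-fold at either age; each age holds a single pair of pools, and the difference was not tested. S100a9 stood at −1.74 at 4 months and 1.45 at 18 months, S100a8 at −1.83 and 1.29, Tac2 at −1.29 and 0.63, and Prl at 4.31 and −1.68.

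In the 18-month columns of the authors' table, neocortex markers stood higher than in the scanner files of the same samples by a median of 0.80 in WT and 1.05 in hetero-KO, and the dentate granule cell markers lower (−1.19 and −1.23). The highest log2 correlation with any scanner file was 0.982, with no constant ratio, which argues against an exchange of columns. RNA of neocortex is a candidate explanation: the smaller neocortex median, 0.80, lay above the bound of 0.5 set for it before the test, although all but 1 of the 20 markers were also measured in the hippocampus arrays. The shift was not specific to neocortex: striatum markers stood higher by 1.08 and 0.86 and immediate early genes by 0.87 and 0.99, and choroid plexus genes lower (−3.64 and −4.11), which RNA of neocortex alone was not shown to explain. Eif2s3y, Uty and Ddx3y were lower in the hetero-KO column than in the WT column by a median of −6.31, with Xist present in both, so the columns may hold mice of the sex makeup seen at 4 months; genotype and age labels are the same in both sources, and no biological explanation was tested.

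At 4 months, genes at least 2-fold apart between hetero-KO and WT may partly reflect different shares of neighbouring tissue: the striatum list had a median of 0.69, while the choroid plexus (−0.46), thalamus and habenula (−0.30) and meningeal (−0.27) lists were lower and the neocortex list stood at 0.04. Eif2s3y, Uty and Ddx3y differed between these pools, and whether different sex makeup accounts for the genes at least 2-fold apart stays open. X- and Y-linked genes were 1.03 times as frequent among these genes as among genes measured on both arrays (15 of 374; 95% Wilson interval 0.63 to 1.68), under the bound of 1.5 but with an interval that reaches over it. An earlier count that also took genes with a bound gave 1.32 (0.97 to 1.79), and neither says anything about autosomal effects of sex. A genotype effect stays among the open explanations.

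Of the age calls, 31.4% were higher under quantile normalization, 67.2% under median scaling and 79.0% with normexp background, against 70.3% in the main setting; with the scaling kept, 31.2% were higher with the mean of a gene's probes and 45.8% without the genotype term. Quantile normalization makes the distributions equal and in part sets this balance itself, so these values leave open whether scaling accounts for it. X- and Y-linked genes were 1.02 times as frequent among the called genes as among those tested (26 of 647, interval 0.70 to 1.48). They were only 3.93% of the genes tested, so they could not have been the source of most calls. The fit also takes the split of Y-linked genes between the 4-month pools as error. This ratio therefore cannot decide whether sex makeup accounts for the calls, and autosomal effects of sex stay open. The thalamus and habenula list had a median of −1.01, so that a different dissection of the pools at the 2 ages could account for the genes that fell with it. Age itself stays open as an untested explanation.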

How the results depend on the processing

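Counts without X- and Y-linked genes or without the regional lists were chosen after the result was seen, and stayed within 1.5 times of the main counts. The genes removed were few, so the counts of genes at least 2-fold apart had little room to move. Without the regional, choroid plexus and meningeal lists, 338 genes rose and 152 fell with age by limma, against 455 and 192. No paired analysis was possible because each group held 1 array; leaving out an array leaves single pairs. Of 207 list medians outside the random range, the sign changed for 90 with the authors' table and for at most 5 under each other choice of scaling, background, spots, probes, filter or list mean. The 18-month columns of that table match none of the scanner files. Its values, here and below, therefore do not show how the results depend on processing. Leaving out a 4-month array changed the sign of 6 of 29 such genotype medians (CA2 pyramidal, MHC class II, endothelial, interneuron, thalamus and habenula, and unfolded protein response lists; the last stood at 0.11 at 4 months and −0.01 at 18 months), and leaving out an 18-month array that of 5 (border macrophage, complement, meningeal, reactive astrocyte and senescence lists). Of 28 such age medians, 2 changed sign without a WT array (endothelial and meningeal lists) and 7 without a hetero-KO array (heat shock, immediate early, interneuron, neocortex, neutrophil and monocyte, oligodendrocyte precursor and unfolded protein response lists). The cause of the changes was not tested unless stated.

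For genotype over both ages (3 higher, 0 lower by limma; 1492 and 1817 unadjusted), the counts were 9 and 5 with normexp background, 8 and 2 with marked spots kept, 8 and 2 with a filter on all 4 arrays, 1 and 7 with the authors' table, 1 and 0 without the age term (389 and 953 unadjusted), 0 and 0 without the filter (1513 and 1944 unadjusted) and 0 and 0 without the variance trend (782 and 2049 unadjusted). For age (455 higher, 192 lower), they were 54 and 118 with quantile normalization, 281 higher with median scaling, 1179 and 313 with normexp, 753 higher with marked spots kept, 29 and 64 with the mean of a gene's probes, 60 and 71 without the genotype term, 4593 and 5281 with the authors' table, and 0 and 0 by limma without the filter (5025 and 2044 unadjusted) or without the variance trend (2770 and 1721 unadjusted).

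Genes at least 2-fold higher and lower in hetero-KO numbered 69 and 27 at 4 months and 25 and 41 at 18 months with normexp, and 842 and 1291, and 1052 and 1073, without the filter, which lets in genes at background. Between the ages they numbered 62 and 70 in WT and 87 and 119 in hetero-KO with normexp, 1143 and 1155, and 1532 and 1160, without the filter, and 981 and 1504, and 862 and 1273, with the authors' table. The genotype by age count was 94 with normexp and 2950 without the filter. The correlation of the mean genotype and age differences was −0.0011 with quantile normalization, 0.0392 with normexp, 0.0011 with the mean of probes, 0.0582 without the filter and 0.201 with the authors' table.

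With the authors' table, whose 18-month columns match none of the scanner files, Zbtb18 stood at −0.0445 for genotype at 18 months. For age it stood at −0.56 and −0.40 in WT and hetero-KO. The age difference took the opposite sign for C4a (−1.15), C4b (−1.02), Clec7a (−0.22), Itgax (−0.11), C3 (−1.19), Dlk1 (−1.09), Avp (−1.10), Opn3 (0.33) and Unc13c (0.13). Signal over background limits the dim genes: 77.9% to 81.9% of spots were well above it.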

Other observations

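In this part the test of transcription running on from the targeted allele was chosen after the result was seen, and the Wilson interval was added after its ratio had been seen.

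Several transcripts near Zbtb18 stood out by genotype. Besides Gm29856 and AK156859, Gm36904 was well above background in hetero-KO alone, at least 4.20-fold higher at 4 months and 4.32-fold at 18 months; its probe lies at −142 kb, on the other side of Zbtb18. The hetero-KO column of the authors' table at 18 months also stood above its WT column for Gm29856 (by 3.98) and AK156859 (by 2.12). Zbtb18 itself differed by −0.20 and 0.18.

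A first hypothesis is that transcription runs on from the targeted allele. The high levels of Gm29856 and AK156859 prompted this hypothesis and are no test of it. The 9 other genes measured on all 4 arrays within 500 kb had a median size of the genotype difference of 0.15, so no wide shift was seen around the locus; Gm36904 was not among those 9 and lies where this would not reach. A second hypothesis is a segment of chromosome 1 of another strain that came with the allele, which could raise or lower genes over a longer stretch or change how probes bind. Of 258 genes measured on all 4 arrays within 10 Mb, 18 had a mean difference of at least 1.5-fold with the same sign at both ages, 6.98% of them and 3.49 times the share elsewhere (95% Wilson interval 2.23 to 5.38). The ratio lay above the bound of 3 set for this hypothesis, but its interval reaches below it, while staying above the 1.5 that would have spoken against it. Both hypotheses stay open.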
